A study of Homo sapiens with 24 samples.

How the data were processed

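H4K20me3 was profiled by CUT&RUN in HN-SCC-151 cells treated for 6 days with DMSO, A-196 at 2.5 µM, control siRNAs (siNC) or siRNAs against SUV420H1. Per the labels' protocols, 500000 cells went into each reaction and libraries were made with the SWIFT Accel-NGS 2S Plus kit. The labels list 24 samples. The 14 H4K20me3 libraries were used (3 DMSO, 3 A-196, 4 siNC and 4 siSUV420H1), grouped by their titles. The other 10 samples (2 IgG, 4 H3K4me3 and 4 H3K27me3 libraries) were not analysed here as measurements of their own.

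Each deposited list gives the start and end of broad peaks in base pairs for 1 library, and no score, enrichment, p-value or read count. Per the submitters' processing notes, the authors worked on hg38 and used cutadapt 4.4, Bowtie, Picard 2.27.3 and bedtools 2.30.0. Per the labels of the deposited lists, duplicate reads were removed and peaks were called for each library alone against 1 IgG library, that of DMSO cells in the inhibitor arm and one with no treatment in its label in the siRNA arm. The peak caller and its settings are not given in the sources used here. All peak ends lay on a 1000 bp grid, the narrowest peak was 5 kb wide and the smallest gap between peaks of a library was 2 kb, so smaller changes of a domain are not visible. The sequencing depth per library was unknown, so no interval or floor that needs it is given; a region without a peak may hold signal below the calling threshold, and a difference in depth or enrichment between libraries can change what was called.

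Coordinates are 1-based on hg38. Gene spans came from a RefSeq table of GRCh38, which holds no strand and no exons. A protein-coding gene was marked where the peaks of a library covered at least 200 bp of its span extended by 2 kb on both sides; the flank intended was upstream only, which needs the strand. Exons, introns, promoters, repeats and GC content were not analysed here. Of the coding symbols, 19866 lay on the primary chromosome sequences and 190 that lay on scaffolds or alternate sequences were left out. Genes without strand or exon data can share a peak with a neighbour or an overlapping gene, and their marks cannot then be told apart.

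For each library the number of peaks, the covered length, the median width and the number of peaks of at least 50 kb were computed, and for each pair of libraries the Jaccard index of covered bases. Within an arm, all peaks were merged into union regions. A region or gene was lost when present in every control and in no treated library, and gained in the opposite case. Group means were compared by exact two-sided permutation tests over all assignments of libraries to groups, covered length on the log2 scale, with Benjamini-Hochberg adjustment over the 3 library measures, the 18 gene lists or the 27 location measures and a threshold of 0.05. Chromosome Y was left out of location measures. The outer 1 Mb of a chromosome was counted from its outermost annotated gene or peak. Counts of lost and gained regions and genes were compared with every other split of the same libraries.

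The gene lists, fixed before the data were examined together with the design, the main tests and most other settings tried, were C2H2 zinc finger genes, interferon-stimulated genes, interferon ligands and receptors, nucleic acid sensing, antigen presentation, chemokines, clustered protocadherins, olfactory receptors, keratins, the epidermal differentiation complex, HOX genes, histone genes, imprinted genes, cancer-testis genes, the H4K20 methylation and heterochromatin machinery, DNA replication licensing and cell cycle, squamous epithelial genes, and markers of other cell types. The number of members marked in controls was set against 10000 random gene sets matched on gene length, and the number lost or kept against 10000 sets matched on control covered length (one-sided). Named genes were, per comparison, the 10 lost genes with the longest covered length in controls, the 10 gained genes with the longest in treated libraries, the 5 other genes with the largest fall and the 5 with the largest rise among those whose groups did not overlap, up to 4 lost and 4 gained members per list, and KMT5B and KMT5C. A gene that this rule names in the siRNA arm is not reported here. Other genes named in a list, in the overlap of the arms or in a wide region were chosen after their values were seen.

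The arms share no H4K20me3 library. Overlaps of their gene lists were tested by Fisher's exact test over genes marked in every control library of both arms for losses and in none for gains. Differences between the arms were tested by exact permutation of the labels within each arm over 51 measures. Alternatives covered the smallest overlap, the definition of a region, the width and number of peaks used, chromosomes, the summary of a group, the replicate block, single libraries left out and, chosen after seeing the data, gene bodies without flanks, 1 gene per region and the omission of chromosomes 13, 14, 21 and X.

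The calling code was tested on simulated data made from the merged regions of the control libraries, with presence drawn at 95% per library and 200 regions seeded as lost and 200 as gained. A region had the same edges in every simulated library. The real A-196 libraries were far less alike, with a mean Jaccard index of 0.315. The rates below thus check the code and do not estimate false calls in the real data. In the inhibitor arm 84.5% of seeded losses and 83.5% of seeded gains were recovered (85.7% expected), with 0 false losses and 1 false gain among 10495 regions. In the siRNA arm 84.5% and 85.5% were recovered (81.5% expected), with 1 false loss and 0 false gains among 17213 regions. Of genes over seeded losses, 86.4% of 44 and 87.5% of 32 were recovered among 19866 genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.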

Results

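H4K20me3, the trimethylated form of lysine 20 of histone H4 that marks silent heterochromatin, was mapped by CUT&RUN in HN-SCC-151, a squamous cell carcinoma line of the head and neck without HPV. In CUT&RUN a nuclease tethered to an antibody releases the DNA wrapped around the marked histones, and the released fragments are sequenced. The series names SUV420H1 (gene symbol KMT5B), an enzyme that methylates H4K20, as the target of both arms. In the inhibitor arm, 3 libraries of cells treated at 2.5 µM with A-196, an inhibitor of SUV420H1 and also of its paralog SUV420H2 (KMT5C), were compared with 3 libraries of cells given DMSO. In the siRNA arm, 4 libraries of cells transfected with siRNAs against SUV420H1 (siSUV420H1) were compared with 4 libraries of cells given control siRNAs (siNC). Treatment lasted 6 days in each arm. The question in both comparisons was where the mark lay in the genome and how its broad domains differed once the enzyme was inhibited or depleted.

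The values were broad peaks on hg38, 1 list per library. The DMSO libraries held 8430 to 8921 peaks over 145 to 153 Mb, and the A-196 libraries 8505 to 13464 peaks over 79.6 to 107 Mb. The siNC libraries held 13818 to 14675 peaks over 183 to 193 Mb, and the siSUV420H1 libraries 9325 to 10203 peaks over 118 to 130 Mb. The lists carried no read counts, so the sequencing depth behind each peak was unknown. A gene was called marked in a library where peaks covered at least 200 bp of its body or of the 2 kb on either side. It was called lost where it was marked in every control library and in no treated library, and gained in the opposite case; regions were called in the same way. KMT5B (chromosome 11, 68154863 to 68213648) and KMT5C (chromosome 19, 55339876 to 55348121) carried no peak in any of the 14 libraries. The RNA and protein of SUV420H1 were not analysed here, so the peak lists do not check the knockdown.

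**Figure D1:**
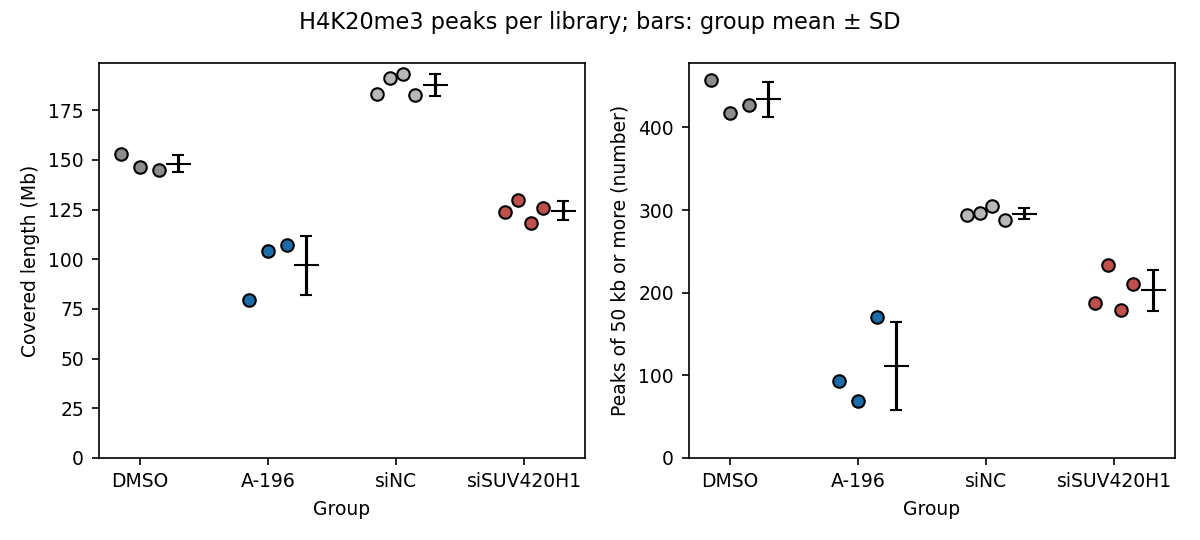
Covered length in Mb (left panel) and number of peaks at least 50 kb wide (right panel) for each library, 1 circle per library, with the group mean ± SD beside it. The A-196 libraries lie at 79.6 to 107 Mb against 145 to 153 Mb for DMSO, and the siSUV420H1 libraries at 118 to 130 Mb against 183 to 193 Mb for siNC.

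After A-196, the broad domain over CXCL9, CXCL10 and CXCL11, interferon-induced chemokines that attract T cells, had no peak left in any of the 3 libraries. In DMSO cells, peaks covered 34 kb ± 0.867 (SD, n = 3) of the stretch from the start of CXCL9 to the end of CXCL11 (chromosome 4, 76001275 to 76036070). Hair and epithelial keratins also carried the mark in DMSO cells and mostly lacked it in A-196 cells: of 55 keratins, 17 ± 1 were marked with DMSO and 2.33 ± 1.53 with A-196 (SD, n = 3). Of 566 C2H2 zinc finger genes, the largest family of human transcription factors, 328 ± 4.58 were marked with DMSO and 333 ± 16.6 with A-196. In this family, 249 of the 302 marked in every DMSO library were marked in every A-196 library. The whole covered length was 148 Mb ± 4.29 with DMSO and 96.9 Mb ± 15 with A-196, 34.6% lower.

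The length of genome under peaks differed by -0.62 on the log2 scale (exact two-sided permutation test, p = 0.1, adjusted p = 0.15 over 3 measures, n = 3 against 3, lower in 3 of 3 A-196 libraries). With 3 libraries against 3, 0.1 is the smallest p that the test can give, so no single value of this arm could pass the threshold of 0.05. Peaks were narrower: their median width was 9.67 kb ± 0.577 with DMSO and 6.33 kb ± 0.577 with A-196 (exact p = 0.1, adjusted p = 0.15, n = 3 against 3, two-sided). Peaks of 50 kb or more numbered 434 ± 21.4 with DMSO and 111 ± 53.3 with A-196 (SD, n = 3). The number of peaks, 8739 ± 269 with DMSO and 10589 ± 2572 with A-196, did not differ beyond the spread between libraries (exact p = 0.3, adjusted p = 0.3, n = 3 against 3, two-sided). The difference of 1850 depended on the libraries and peaks used: it was 413 without A-196 replicate 2, 2892 without replicate 1 (exact p = 0.1, n = 3 against 2), 2131 with peaks within 5 kb merged (exact p = 0.1, n = 3 against 3) and -2409 among peaks at or above the median width of the arm.

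Of the 5932 regions marked in every DMSO library, 1615 were lost and 1937 were marked in every library of both groups; 286 regions were gained. The widest lost regions measured 70 kb each. That of CXCL9, CXCL10 and CXCL11 (chromosome 4, 76000001 to 76070000) also holds part of ART3, an ADP-ribosyltransferase family gene, and the other (chromosome 7, 84430001 to 84500000) overlaps SEMA3A, which encodes an axon guidance factor, and runs past the end of that gene. Among 19866 protein-coding genes, 353 lost the mark and 161 gained it. The mean number of marked genes per library did not fall, at 2350 ± 40.3 with DMSO and 2710 ± 848 with A-196 (SD, n = 3, exact two-sided permutation p = 0.9). A-196 replicate 2 had the most, 3684. The A-196 libraries resembled each other little, with a mean Jaccard index of covered bases of 0.315 within the group against 0.750 within DMSO. Between DMSO and A-196 it was 0.302, hardly lower than within A-196. A-196 replicate 3 shared 0.397 to 0.405 with the DMSO libraries and 0.385 and 0.283 with the other A-196 libraries. The counts also changed when single libraries were left out. That makes the rule laxer, so gene counts could only rise. Among peaks at or above the median width of the arm, 1765 regions were lost but only 56 regions and 23 genes gained. Most gains thus rested on narrower peaks. Without A-196 replicate 1, 918 regions and 348 genes were gained. Without A-196 replicate 2, 596 regions were gained. Without A-196 replicate 3, 2466 regions and 552 genes were lost and 922 regions and 441 genes gained. Leaving out 1 DMSO library gave 398 to 414 genes lost and 168 to 172 gained.

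The lost genes with the longest covered length in DMSO were ART3, with 68.5 kb ± 3.21 (chromosome 4, 76011190 to 76112786), PDE6A, a rod photoreceptor phosphodiesterase, with 41.3 kb ± 3.06 (chromosome 5, 149857953 to 149944793), and BTG4, with 36.8 kb ± 2.61 (chromosome 11, 111383826 to 111514725), each SD with n = 3. IRAG2 had 33.3 kb ± 7.57 and the steroid glucuronidating enzyme UGT2B17 29.2 kb ± 2.83. SLC38A11 (26 kb ± 4.04), OLR1, the receptor for oxidised low-density lipoprotein (22 kb in each library), PIGR, the polymeric immunoglobulin receptor (20.5 kb ± 1.31), LURAP1L (20 kb ± 2) and PRR16 (19 kb ± 2.65) completed this group. All 10 were listed at 0 kb in each A-196 library. The span of PDE6A overlaps that of PPARGC1B, that of IRAG2 overlaps DNAI7, and that of OLR1 overlaps TMEM52B. Long genes that kept part of the mark had the largest differences. RAD51B (chromosome 14, 67819779 to 68683096), had 360.1 kb ± 17.6 with DMSO and 46.4 kb ± 18.2 with A-196. SEMA3A had 222 kb ± 13.2 and 31.3 kb ± 2.08, GLIS3 199.9 kb ± 14 and 33.7 kb ± 21, FSTL5 188 kb ± 17.3 and 27.3 kb ± 19.3, and PIEZO2, a mechanosensitive channel, 191 kb ± 1.53 and 34.7 kb ± 28.5.

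Interferon-stimulated genes were marked in DMSO more often than length-matched gene sets (10 of 50 in each library, 99.4th percentile of 10000 sets). Zinc finger genes, chemokines, clustered protocadherins, keratins and the epidermal differentiation complex stood higher, each at percentile 100. Olfactory receptors stood at percentile 0.065. With A-196, 6 ± 1 of the 50 interferon-stimulated genes were marked. None of the 50 was gained and 5 were lost, among them RTP4 (6.62 kb in each DMSO library), IFI44 (5.21 kb ± 1), IFI44L (4.48 kb ± 1.15) and XAF1 (2.55 kb ± 1.73). Of 39 chemokines, 11 were marked in each DMSO library and 3.67 ± 2.08 with A-196; 7 were lost in 4 regions, including CXCL9 (7.84 kb ± 1.53), CXCL11 (6.39 kb in each library), CXCL10 (6.38 kb) and CXCL2 (6.16 kb), the last a neutrophil chemokine. Keratins lost 8 of the 13 members marked in every DMSO library, in 6 regions: KRT7 of simple epithelia (12.8 kb ± 2.65) and the hair keratins KRT39 (12.5 kb in each library), KRT33B (10.3 kb) and KRT86 (9.69 kb ± 4.93) led. Genes of the epidermal differentiation complex, which build the cornified envelope, went from 23.7 ± 1.15 to 11.3 ± 3.21 marked members of 54. Of these, 6 were lost, including TCHH, which encodes trichohyalin (9.98 kb ± 0.256), S100A12 (5.37 kb ± 0.936), LCE1B and SPRR1A. Among peaks at or above the median width of the arm, the lost calls of IFI44, IFI44L, XAF1, S100A12 and LCE1B ended; with gene bodies alone, those of XAF1, LCE1B and SPRR1A did.

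Marked olfactory receptors numbered 9.67 ± 0.577 of 389 with DMSO and 26.3 ± 3.51 with A-196, with 5 gained and OR5K2 lost; the gained members included OR4K1 (6.25 kb ± 1.39 with A-196), OR4K17, OR8I2 and OR5D3, and those 4 calls ended among peaks at or above that median. Imprinted genes numbered 4.67 ± 0.577 of 37 with DMSO and 10.3 ± 1.53 with A-196. The 3 gained were SNRPN in the Prader-Willi region (24.4 kb ± 31.8) and the neighbours ZIM2 (17.5 kb ± 2.5) and PEG3 (5.61 kb ± 1.54), whose annotated spans overlap on chromosome 19; in none of the 3 was any base covered in all A-196 libraries. Clustered protocadherins, cell adhesion genes with stochastic promoter choice, kept the mark: 17 of the 18 members marked in every DMSO library were marked in every A-196 library, against a median of 10 in sets matched on DMSO covered length. Fibroblast, endothelial and leukocyte markers were marked at 5.33 ± 0.577 of 23 members with DMSO and 3.67 ± 1.53 with A-196, with none lost. Squamous epithelial and carcinoma genes stood at 7.33 ± 1.15 and 6 ± 3.46 of 33.

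None of the 18 lists passed adjustment on its number of marked members. For interferon-stimulated genes, chemokines, keratins, the epidermal differentiation complex, olfactory receptors and imprinted genes the groups did not overlap (exact two-sided permutation p = 0.1, the smallest possible, adjusted p = 0.3 for each of these lists, n = 3 against 3). Against 10000 gene sets matched on DMSO covered length, keratins lost more members than chance gave (8 against a median of 3, adjusted one-sided permutation p = 0.0192) and zinc finger genes fewer (5 against a median of 31, adjusted one-sided permutation p = 0.0012, the smallest the draws can give). Chemokines missed that threshold after adjustment (7 against a median of 4, adjusted one-sided permutation p = 0.184), as did interferon-stimulated genes (5 against 3, adjusted one-sided permutation p = 0.461). The epidermal differentiation complex lost as many as the median of matched sets (6 against 6). Members of one list can lie under one peak, and genes are not independent, so these set tests overstate the evidence.

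The 161 gained genes were long, with a median of 240.7 kb against 24.5 kb for all genes, and in 105 of them no stretch of 200 bp was covered in every A-196 library. Among the 161, the longest covered lengths with A-196 were those of PTPRT (71 kb ± 35.7, with 4 kb common to the 3 libraries) and GPC5 (64.3 kb ± 26.6, 4 kb). CDH12 had 63 kb ± 26.2 with 5 kb in common, and GABRG3 51 kb ± 30.4 with 10 kb in common. CTNND2 (39 kb ± 14.7), CALN1 (36.3 kb ± 43.4), CSMD1 (31 kb ± 17.5), CNTN4 (29.7 kb ± 9.07) and GPC6 (29.3 kb ± 14.7) had no base covered in all 3 libraries. LOC112268076 had 37.1 kb ± 30.9, of which 5 kb were common. The largest higher value among genes already marked in DMSO was that of PTPRN2, a receptor-type phosphatase of secretory vesicles (chromosome 7, 157539056 to 158587823), with 52.7 kb ± 4.93 with DMSO and 198 kb ± 30.5 with A-196, and 92 kb common to the A-196 libraries. The gained calls of CDH12, GABRG3, LOC112268076, CALN1, CNTN4 and GPC6, and of the imprinted SNRPN and PEG3, ended among peaks at or above the median width of the arm. ZNF469 had 9.67 kb ± 0.577 and 37.9 kb ± 9.60. MDGA2 (1.67 kb ± 2.89 and 51.7 kb ± 16.9) had no base in common, and neither did LRRC4C, at 28 kb ± 8.54 with A-196. The widest gained region on chromosome 19 held ZNF331 and DPRX (53569001 to 53606000). Covered length was lower in every A-196 library than in every DMSO library for 1095 genes and higher for 217, beside 5613 genes marked in any library of the arm. Chance gives at most 10% of genes in both directions together, and fewer where libraries tie at 0 kb.

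By chromosome, covered length with A-196 was lower on 19 of 23 chromosomes. It differed by -60.1% on chromosome 4 (8.23 Mb ± 0.381 against 3.28 Mb ± 0.664), -57.8% on chromosome 6 and -56.9% on chromosome 12. On chromosome 19, which holds more zinc finger genes than any other, it was 6.94 Mb ± 0.369 with DMSO and 7.85 Mb ± 1.99 with A-196, and the share of all covered bases lying there was 4.69% ± 0.144 and 8.13% ± 1.65 (SD, n = 3). The outer 1 Mb of the chromosomes held 2.06% ± 0.0731 of covered bases with DMSO and 3.56% ± 0.365 with A-196. The groups did not overlap for 21 of the 27 location measures, 9 higher and 12 lower with A-196, and none passed adjustment (exact two-sided permutation p = 0.1 for each of those 21, smallest adjusted p = 0.129, n = 3 against 3).

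**Figure D2:**
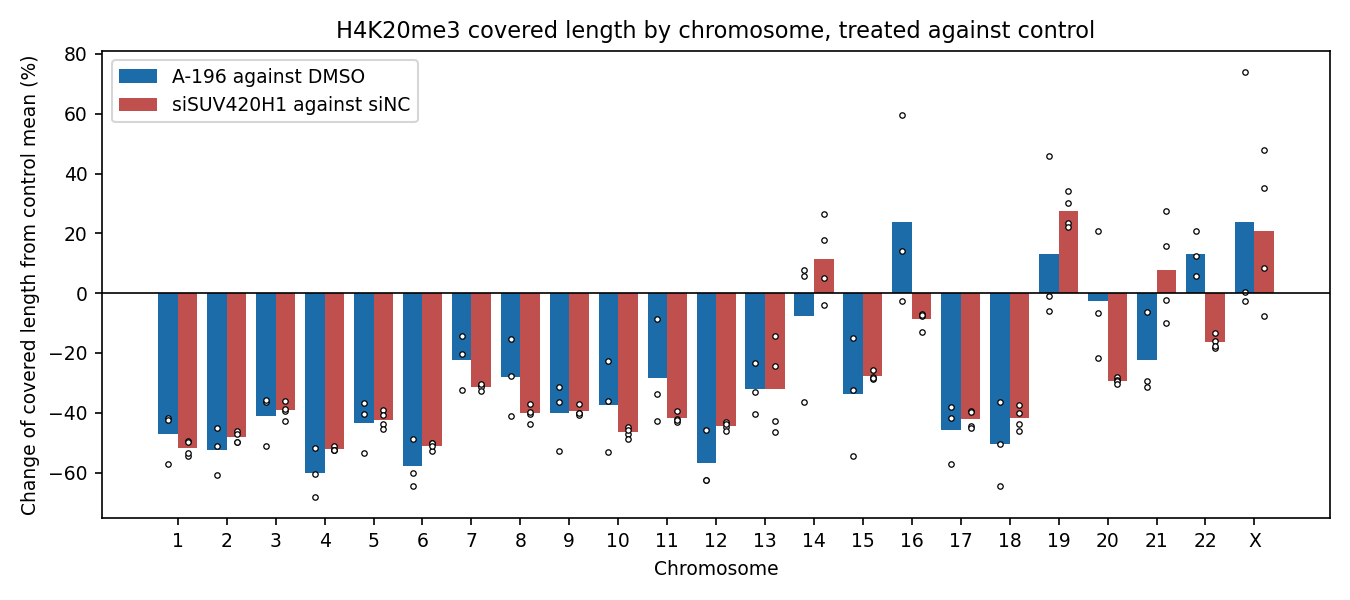
Change of covered length (% of the control mean, vertical axis) on each chromosome (horizontal axis) for A-196 against DMSO and siSUV420H1 against siNC. Bars are group means and circles single treated libraries; chromosome 4 lies at -60.1% and -52.1%, while on chromosome 19 the siSUV420H1 mean is 27.6% above siNC and every circle of that group is above 0.

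After siSUV420H1, the chemokines CXCL9, CXCL10 and CXCL11 also had no peak within 2 kb in any of the 4 libraries, where siNC peaks covered 32.9 kb ± 3.26 (SD, n = 4) of the stretch from CXCL9 to CXCL11. IFI16, a sensor of nuclear and cytosolic DNA, CDK1, the mitotic cyclin-dependent kinase, and ZFAT, an imprinted zinc finger gene, lost the mark in the same way. The covered length of the genome fell by 33.7%, from 188 Mb ± 5.49 to 124 Mb ± 4.70 (SD, n = 4), and the number of peaks fell by 30.8%, from 14270.2 ± 420.2 to 9875 ± 408. Zinc finger genes numbered 354 ± 2.99 and 352 ± 2.45 marked of 566, and 323 of the 341 marked in every siNC library stayed marked in every siSUV420H1 library. The covered length of chromosome 19 rose from 6.68 Mb ± 0.172 to 8.51 Mb ± 0.378.

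Both falls held in 4 of 4 siSUV420H1 libraries against every siNC library (exact two-sided permutation p = 0.0286, the smallest possible with n = 4 against 4, adjusted p = 0.0429 over 3 measures; log2 change of covered length -0.59). With group medians in place of means the differences were -4309 peaks and -0.58 (exact permutation p = 0.0571, n = 4 against 4). That is the smallest p this test can give with medians of 4 libraries, so neither could pass the threshold. The median width was 9 kb in every library of both groups. Peaks of 50 kb or more numbered 296 ± 7.04 with siNC and 203 ± 24.9 with siSUV420H1 (exact two-sided permutation p = 0.0286, n = 4 against 4), and marked genes 3185 ± 53.3 and 2353 ± 84.5. The series' design text gives 3 dishes per condition, fewer than the 4 libraries of each group, so some libraries of a group may come from the same dish and the p-values measure the spread between these libraries.

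Of 10254 regions marked in every siNC library, 3301 were lost, 5084 were marked in every library of both groups, and 279 were gained. The widest lost region lay over RNLS (chromosome 10, 88467001 to 88558000, 91 kb) and another over RADX and RNF128 (chromosome X, 106667001 to 106715000, 48 kb). Among protein-coding genes 593 lost and 68 gained the mark; the mean Jaccard index was 0.772 within siNC, 0.689 within siSUV420H1 and 0.447 between them. The split between lost and gained depended on the number of peaks: with the same number of widest peaks taken from every library, 279 genes were lost and 187 gained, and 1442 regions lost and 656 gained.

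**Figure D3:**
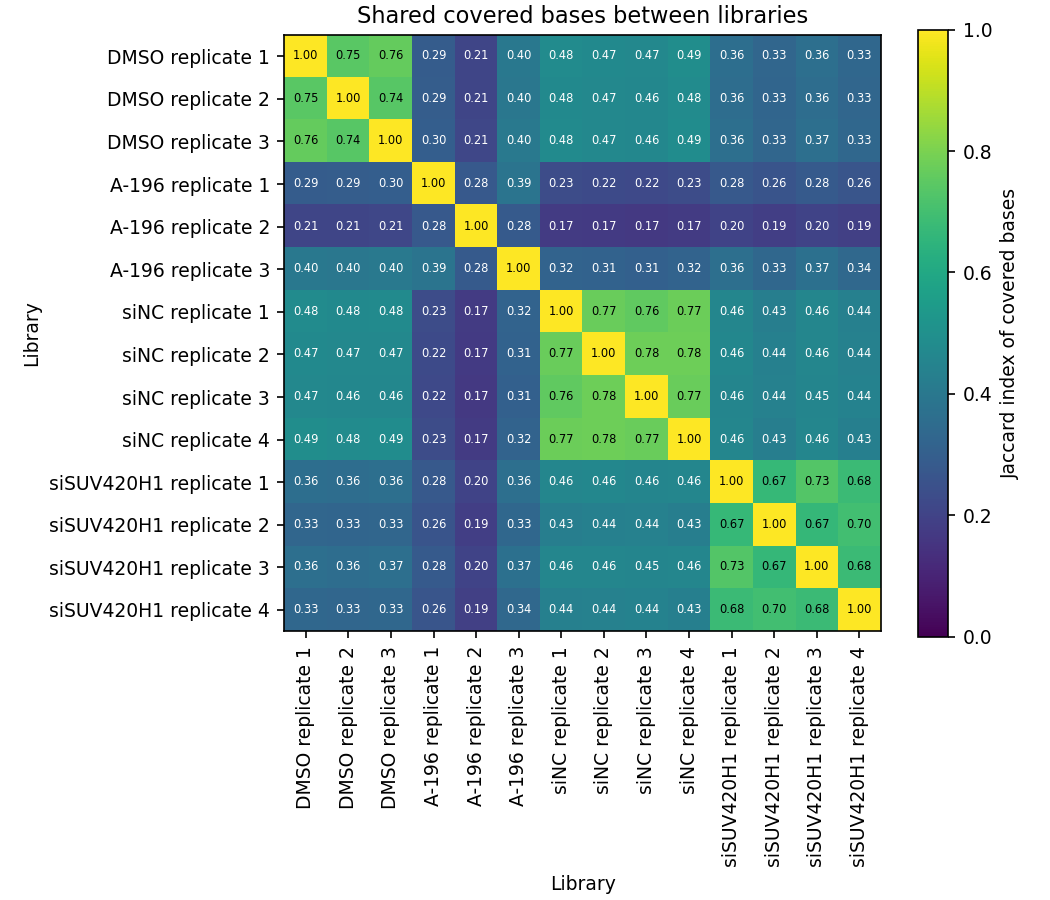
Jaccard index of covered bases (colour and printed value, no unit) for each pair of the 14 libraries, which stand on both axes. DMSO pairs average 0.750, siNC pairs 0.772 and siSUV420H1 pairs 0.689, whereas A-196 pairs average 0.315, close to the 0.302 of pairs between DMSO and A-196.

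The lost genes with the longest covered length in siNC were TPRG1, beside TP63, with 74.3 kb ± 3.40 (chromosome 3, 188997227 to 189325304), TRDN, which encodes triadin of the sarcoplasmic reticulum, with 57.3 kb ± 11.3 (chromosome 6, 123216339 to 123636950), and the transcription factor SOX6, with 54.3 kb ± 4.92 (chromosome 11, 15966449 to 16738477), each SD with n = 4. MLIP had 51.5 kb ± 5.58, PDE3B, a cyclic nucleotide phosphodiesterase, 40.3 kb ± 4.27, CLDN10, a tight junction claudin, 37.5 kb ± 3.11 and SIRPG 36.5 kb ± 3.10. The transcription factor DACH1 (35.3 kb ± 2.5), the killer cell receptor KLRG1 (33.9 kb ± 8.55) and PHF24 (33 kb ± 3.16), whose span also holds the chemokine genes CCL19 and CCL21, were the others. All 10 were listed at 0 kb in every siSUV420H1 library. The span of KLRG1 overlaps those of A2M and PZP, that of PDE3B overlaps CYP2R1, and that of CLDN10 overlaps DZIP1. Partial differences were largest in long genes: CSMD3 had 395.5 kb ± 29.5 with siNC and 158 kb ± 16.3 with siSUV420H1, the protocadherin PCDH15 192.5 kb ± 18.8 and 21.5 kb ± 3.32, KLHL1 232 kb ± 36.8 and 67.7 kb ± 29.7, MACROD2 209 kb ± 13.5 and 61.5 kb ± 4.65, and PCDH9 169 kb ± 16.8 and 33.5 kb ± 7.59.

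Interferon-stimulated genes numbered 15.3 ± 0.957 marked members of 50 with siNC and 6.75 ± 1.89 with siSUV420H1 (SD, n = 4). Of these 5 were lost, including XAF1 (8.25 kb ± 0.957), RTP4 (6.12 kb ± 0.577), IFIT3 (4.25 kb ± 0.5) and GBP1 (2.21 kb in each siNC library), and 1, the RNA helicase DDX60, was gained with 12 kb ± 3.16. Chemokines stood at 9.25 ± 0.5 and 2.75 ± 0.5 of 39, with 6 lost in 5 regions: CXCL9 (6.51 kb ± 3.37), CXCL11 (6.39 kb in each library), CXCL10 (6.38 kb), CXCL2 (4.19 kb ± 1.40), CXCL8 and CXCL1. Antigen presentation genes went from 2.75 ± 0.5 of 35 to 0 in every library, with ERAP1 (8.75 kb ± 4.35) and ERAP2 (5.01 kb ± 0.00850), aminopeptidases that trim peptides for MHC class I, lost under 1 region. Among nucleic acid sensors, IFI16 was lost (9.25 kb ± 0.5). Its annotated span overlaps those of PYDC5 and AIM2, and that of IFIT3 overlaps LIPA, so these marks may be shared.

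Keratins stood at 12 ± 0.816 of 55 with siNC and 4.25 ± 1.26 with siSUV420H1, and 5 were lost, including KRT31 (7.89 kb in each siNC library), KRT33B (6.19 kb ± 3.57), KRT16 (2.47 kb ± 0.957) and KRT84. The epidermal differentiation complex had 18 ± 1.63 and 8.25 ± 1.26 of 54, with 7 lost, among them SPRR4 (4.82 kb ± 0.5), LCE1F (2.86 kb in each library), LCE1C and LCE3C. Squamous epithelial and carcinoma genes had 7.75 ± 0.5 and 4.25 ± 0.5 of 33, and the lost members included FAT1, an atypical cadherin often mutated in this carcinoma (6.25 kb ± 1.5). The 2 lost genes of the cell cycle list were CDK1 (13.2 kb ± 1) and MYC (1.57 kb), and the 2 lost imprinted genes were ZFAT (22.3 kb ± 3.40) and FAM50B (6.36 kb ± 0.5). Markers of other cell types had 8.50 ± 1 and 5 of 23, with the smooth muscle actin ACTA2 (8 kb), the endothelial PECAM1 (7 kb ± 1.63) and the fibroblast proteoglycan DCN (6.75 kb ± 1.5) lost. The annotated span of ACTA2 overlaps that of FAS, so its mark may be shared. Clustered protocadherins had 21.3 ± 0.5 and 23.5 ± 1 of 53, and all 20 marked in every siNC library stayed marked.

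For interferon-stimulated genes, antigen presentation, chemokines, keratins, the epidermal differentiation complex, squamous genes and markers of other cell types, all siSUV420H1 libraries had fewer marked members than all siNC libraries, and for protocadherins more. Each of these 8 lists gave the smallest possible p and missed the threshold over the 18 lists (exact two-sided permutation p = 0.0286, adjusted p = 0.0643, n = 4 against 4). Against sets matched on siNC covered length, zinc finger genes lost fewer members (9 against a median of 51, adjusted one-sided permutation p = 0.0011, the smallest the draws can give), protocadherins kept more (adjusted one-sided permutation p = 0.0374) and no list passed for more losses. Chemokines had 6 against a median of 3 (adjusted one-sided permutation p = 0.356), and keratins, which passed in the inhibitor arm, 5 against 4 (adjusted one-sided permutation p = 0.626). Interferon-stimulated genes lost 5 against 5 (adjusted one-sided permutation p = 0.778) and the epidermal differentiation complex 7 against 6 (adjusted one-sided permutation p = 0.626), about as many as matched sets. As in the inhibitor arm, members of a list can lie under 1 peak and genes are not independent, so these set tests overstate the evidence. The number of regions over the protocadherins kept is not given here. With the same number of widest peaks from every library, the lost calls of XAF1, RTP4, IFIT3, ERAP1, ERAP2, KRT16, KRT84, SPRR4, LCE1C, FAT1, PECAM1 and DCN ended, whereas those of CXCL9, CXCL10, CXCL11, IFI16, CDK1 and ZFAT held. With the gene body alone, without its flanks, those of CXCL9, KRT33B, KRT16, KRT84 and MYC ended. Among peaks at or above the median width of the arm, those of GBP1, LCE1F and ACTA2 ended too, along with XAF1, RTP4, IFIT3, ERAP1, ERAP2, KRT16, KRT84, SPRR4, LCE1C, FAT1, PECAM1 and DCN. CXCL2 kept 0.146 kb of covered length with siSUV420H1, under the 200 bp that mark a gene.

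**Figure D4:**
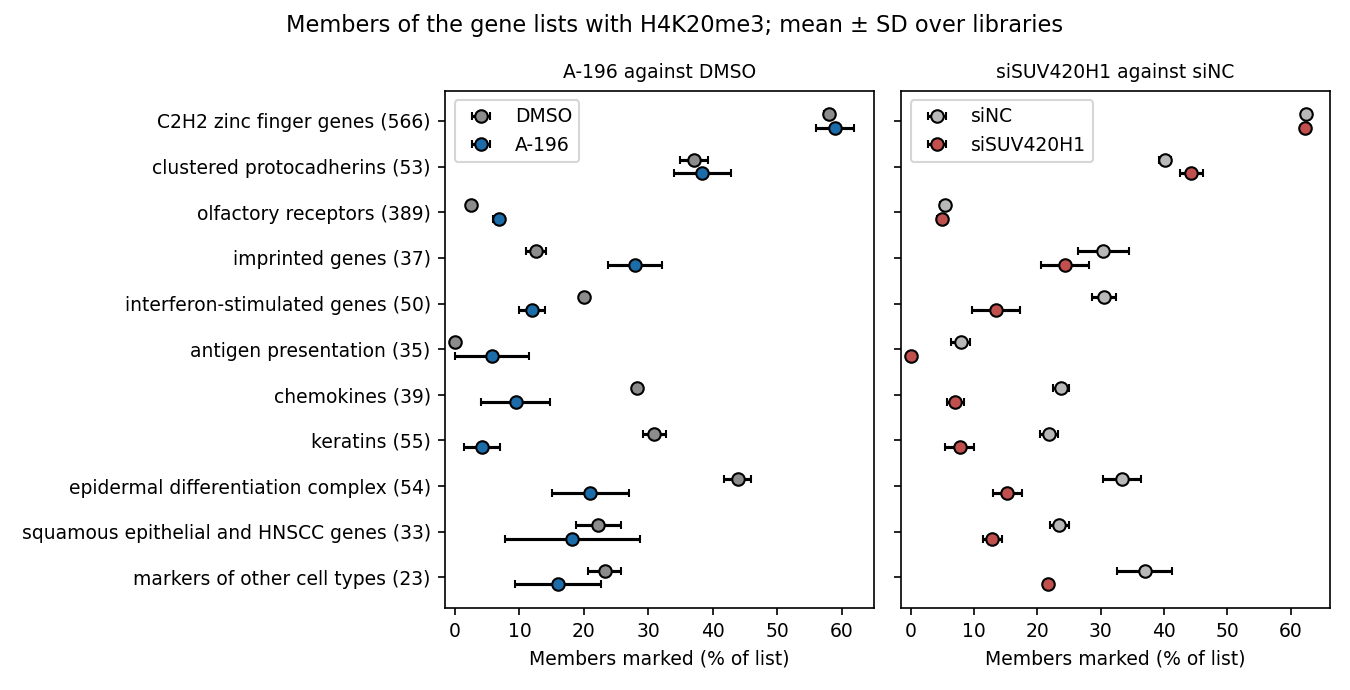
Share of each gene list marked by H4K20me3 (% of members on the horizontal axis, lists with their number of members on the vertical axis), as mean ± SD over 3 libraries per group for DMSO and A-196 (left) and 4 for siNC and siSUV420H1 (right). Keratins go from 17 to 2.33 marked members with A-196 and from 12 to 4.25 with siSUV420H1, while marked zinc finger genes number 328 and 333, and 354 and 352, of 566.

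Gained genes in this arm were fewer, and 61 of the 68 had a stretch covered in every siSUV420H1 library. Several lay in zinc finger genes of chromosome 19: ZNF419 gained 10.8 kb ± 1 and ZNF582 10 kb ± 3.34, and ZNF34 on chromosome 8 gained 9.78 kb ± 3.37. ALMS1, the Alström syndrome gene, gained 11.5 kb ± 3, THAP6 10.8 kb ± 3.86, PPP2R2C 9.75 kb ± 0.957 and LSS, which encodes lanosterol synthase, 9.75 kb ± 0.5. The longest covered lengths were those of CDH12 (21.5 kb ± 14.3) and NRG3 (17 kb ± 15.4), with no base covered in all 4 libraries. Among peaks at or above the median width of the arm, the gained calls of CDH12, NRG3, DDX60, ALMS1, THAP6 and ZNF34 ended, and that of ZNF34 also with the same number of widest peaks. Genes already marked in siNC with the largest higher values were GPC5 (17.3 kb ± 11 with siNC and 208 kb ± 106 with siSUV420H1), LRFN5 on chromosome 14 (137 kb ± 43.4 and 241 kb ± 21.2), CNTN4 (15.5 kb ± 20.8 and 104 kb ± 54.2), SNTG1 (34 kb ± 12.4 and 112 kb ± 52.5) and CNTN6 (20.8 kb ± 3.80 and 80.4 kb ± 33.8). Covered length was lower in every siSUV420H1 library than in every siNC library for 1338 genes and higher for 413, beside 3959 genes marked in any library of the arm. Chance gives at most 2.86% of genes in both directions together, and fewer where libraries tie at 0 kb.

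Covered length fell on 19 of 23 chromosomes. It fell by 52.1% on chromosome 4, from 12.8 Mb ± 0.555 to 6.15 Mb ± 0.0775, and fell by 8.70% on chromosome 16, the smallest of these falls (exact two-sided permutation p = 0.0286, adjusted p = 0.0321 for each of the 19, n = 4 against 4). Chromosome 19 was the only one on which it rose by the same test, in 4 of 4 libraries (exact permutation p = 0.0286, adjusted p = 0.0321, n = 4 against 4). Its share of covered bases rose from 3.56% ± 0.0648 to 6.85% ± 0.503, and that of the outer 1 Mb of chromosomes from 1.74% ± 0.0373 to 2.90% ± 0.143. On chromosomes 14, 21 and X the means were higher in Mb with siSUV420H1 and the groups overlapped (exact p = 0.229, 0.429 and 0.2, n = 4 against 4, two-sided). In shares, 23 of 27 location measures passed adjustment, 9 higher and 14 lower (exact permutation test, adjusted p = 0.0335 for each, n = 4 against 4). Covered length over protein-coding genes fell from 47.2 Mb ± 1.43 to 34.1 Mb ± 0.419 (exact permutation p = 0.0286, adjusted p = 0.0321, n = 4 against 4), by less than elsewhere. The resulting rise in their share, from 25.1% ± 0.0986 to 27.4% ± 1.06, missed the threshold when any 1 of the siNC libraries was left out (exact p = 0.0571, n = 3 against 4).

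The arms had lost genes in common. Of 1668 genes marked in every control library of both arms, 241 were lost with A-196 and 245 with siSUV420H1, and 99 were lost in both, where independent lists would share 35.4 (odds ratio 6.12, two-sided Fisher's exact test, p = 1.25e-28). CXCL9, CXCL10, CXCL11, CXCL2, RTP4, XAF1, KRT31, KRT33B, LCE1B, LCE1C, ZNF281 and ZNF474 were among the 99. Retained genes overlapped as well: 769 genes were marked in every library of both arms, against 626 for independent lists (odds ratio 7.76, two-sided Fisher's exact test, p = 1.21e-60). Genes gained in both arms were 3, FRG2C, CDH12 and TMEM132D, against 0.339 for independent lists (odds ratio 9.55, two-sided Fisher's exact test, p = 0.00473). Genes are not independent observations, so these p-values describe the gene lists and not the libraries. These overlaps were not matched on control covered length. A gene with little covered length or a weak control peak may lose its call in any library that calls less. The overlaps of lost and retained genes therefore do not tell a shared effect on the enzyme from this. The overlap of gained genes was not matched on gene length, and gained genes were long in both arms. CDH12 spans 1103 kb, so scattered peaks may reach it in both arms, and its call ended among wider peaks in both. FRG2C (chromosome 3, 75664328 to 75667173) is short. With 3 genes, this overlap does not establish a shared gain.

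**Figure D5:**
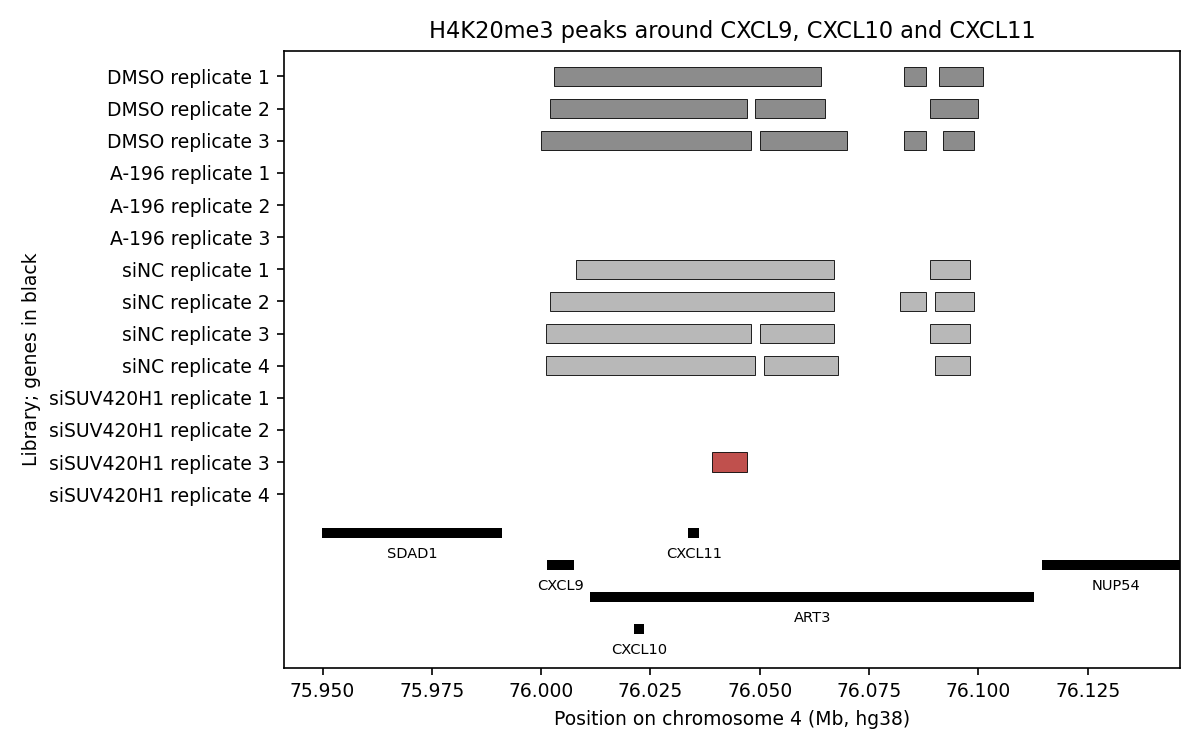
Peaks of each of the 14 libraries (1 line per library on the vertical axis) around CXCL9, CXCL10 and CXCL11 by position on chromosome 4 in Mb, with protein-coding genes in black. All 7 control libraries carry peaks over CXCL10, CXCL11 and ART3, and 6 of them over CXCL9, next to which the peak of siNC replicate 1 starts at 76008001. No A-196 library has a peak here. The only peak among the siSUV420H1 libraries is that of replicate 3, 8 kb wide at 76039001 to 76047000.

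The change of covered length did not differ detectably between the arms (difference -0.03 on the log2 scale, exact permutation of labels within arms, p = 0.853, 3 against 3 and 4 against 4 libraries, two-sided). Of 51 measures compared in this way, none passed adjustment. The smallest adjusted value, 0.0971, was shared by the share of bases on chromosome 8, the number of peaks and marked antigen presentation genes, which differed by 2 with A-196 and by -2.75 with siSUV420H1. The test has little power where both arms hold an effect, because the shuffled labels carry those effects, and the arms were called against different IgG libraries. DMSO and siNC libraries, both without the active treatment, shared a mean Jaccard index of 0.475, below the 0.750 and 0.772 within each.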

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

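A single library stood apart from the other 3 of its group in 16 of 100 group values tested by Dixon's ratio. Chance flags about 1 in 20 groups of continuous values, but 13 of the 16 were small list counts on which the other 3 libraries tied, so that a difference of 1 or 2 genes sets the ratio to 1, and the number of such values says nothing about chance. siNC replicate 2 had 2 marked antigen presentation genes against 3 in the others, 10 chemokines against 9 and 10 markers of other cell types against 8. siNC replicate 1 had 0 cancer-testis genes against 1, 4 cell cycle genes against 5, 7 squamous genes against 8 and 54.6% of its covered bases outside annotated genes, the highest of its group. siNC replicate 4 had 22 marked protocadherins against 21. siNC replicate 3 had 2.66% of its covered bases on chromosome 11, the lowest, and 2.10% on chromosome 21, the highest.

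Among the siSUV420H1 libraries, replicate 1 had 2 marked chemokines against 3, 1 cancer-testis gene against 2 and 5 squamous genes against 4. Replicate 2 had 25 protocadherins against 23. Replicate 4 had 0 interferon ligand or receptor genes against 1 and 4 cell cycle genes against 3.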

How the results depend on the processing

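The gene body alone, 1 gene per region and the omission of chromosomes 13, 14, 21 and X were chosen after seeing the data. Of 242 alternative values for the comparisons, 207 kept their direction and their side of the threshold or stayed within 1.5 times the count, 27 counts moved further, 2 changed sign, 2 passed the threshold newly and 4 no longer did; the cause of these was not tested except where the alternative's construction gives it. A-196 against DMSO: with only peaks in the upper part by width, the difference in the number of peaks was -2409, and 56 regions and 23 genes were gained. With the larger part of a region required to be covered, 2691 regions were lost, and with 5 kb bins 8595 bins, since wide regions count several times. With 1 library of each group allowed to differ, a laxer rule, 4345 regions and 954 genes were lost and 2083 and 766 gained. With the same number of widest peaks per library, 107 genes were gained. Leaving out 1 library, also a laxer rule, gave 1836 to 2466 regions lost, 307 to 922 regions gained, 397 to 552 genes lost and 168 to 441 genes gained. Regions gained were 918 without A-196 replicate 1, 596 without replicate 2 and 922 without replicate 3, genes gained 348 without replicate 1 and 441 without replicate 3, and without replicate 3 regions lost 2466 and genes lost 552. siSUV420H1 against siNC: the median width differed by -1 kb with only the wider peaks and with peaks within 5 kb merged (exact p = 0.0286 in each, n = 4 against 4). With the wider peaks 183 regions were gained. With 5 kb bins 9447 were lost and 878 gained, and with 1 library of each group allowed to differ 5256 regions and 913 genes were lost and 922 and 176 gained. With the same number of widest peaks, 1442 regions and 279 genes were lost and 656 and 187 gained. With group medians, the number of peaks differed by -4309 and covered length by -0.58 on the log2 scale (exact permutation p = 0.0571, n = 4 against 4, the smallest that medians allow). With a replicate block the differences were -4396 peaks and -0.59 (exact sign-flip p = 0.125, the smallest that 4 pairs allow). Same-numbered libraries did not deviate together, with correlations from -0.0872 to 0.0425, and 1 library in each arm correlated best with its own number. The difference between the arms in covered length was 11.9 when taken in Mb, of the other sign (exact permutation p = 0.743, 3 against 3 and 4 against 4 libraries). Of the values of single named genes, 736 of 768 in the inhibitor arm and 922 of 980 in the siRNA arm kept their call. The promoter-only alternative and the median peak score were not run, since they need the strand and a score. Depth was unknown and limits every count of absent peaks.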

Other observations

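The comparison of covered length with depth and enrichment, the gene length placements and the counts of other splits were chosen after the results were seen; the tests of zinc finger genes were not. HOX genes and histone genes carried no H4K20me3 peak in any DMSO, siNC or siSUV420H1 library, and a mean of 1 ± 1.73 of 39 HOX genes and 0.667 ± 1.15 of 71 histone genes were marked with A-196 (SD, n = 3). Cancer-testis genes were marked at 0.333 ± 0.577 of 95 with DMSO and 5.33 ± 4.51 with A-196, and at 0.750 ± 0.5 with siNC and 1.75 ± 0.5 with siSUV420H1 (n = 4), where MAGEB17 was gained. Genes of the H4K20 methylation and heterochromatin machinery stood at 1 and 3 ± 3.46 of 31 in the inhibitor arm, and at 3 and 3.50 ± 0.577 in the siRNA arm. DNA replication and cell cycle genes stood at 3.67 ± 0.577 and 3 ± 1.73 of 41 with A-196, and at 4.75 ± 0.5 and 3.25 ± 0.5 with siSUV420H1. Nucleic acid sensing genes stood at 3.67 ± 0.577 and 3 ± 1 of 24, and at 2.5 ± 0.577 and 1.5 ± 0.577. Interferon ligands and receptors stood at 0 and 0.333 ± 0.577 of 27, and at 1 and 0.750 ± 0.5. Antigen presentation genes stood at 0 and 2 ± 2 of 35 with A-196. With siSUV420H1, olfactory receptors went from 21 ± 2.94 to 19.3 ± 3.30 of 389 and imprinted genes from 11.3 ± 1.5 to 9 ± 1.41 of 37. None of these differences passed adjustment.

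The control groups of the arms differed most on chromosome 14. In the 5 Mb from 25000001 to 30000000, peaks covered a mean of 26.3 kb with DMSO and 2744 kb with siNC, and from 40000001 to 45000000 3.33 kb and 1848 kb. The A-196 means there were 509 kb and 262 kb and the siSUV420H1 means 3190 kb and 3024 kb. The arms differ in treatment vehicle, IgG library and possibly in culture, which cannot be told apart here, and no explanation was tested; within each arm the comparison does not cross this difference, and without chromosomes 13, 14, 21 and X the covered length differed by -0.69 and -0.72 on the log2 scale.

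Covered length was lower in both treated groups. If lower depth only removed peaks, a shallower library would call part of what the controls call. Yet at least 26.5% of the covered bases of each A-196 library lay outside every DMSO peak. Of a DMSO library, at most 9.19% lay outside the others. In the siRNA arm it was 11.5% against 6.35%. These values argue against a plain thinning of the control peaks. They cannot exclude low depth or quality that also calls scattered peaks, because the depth was unknown. Enrichment weaker everywhere predicts less covered length on chromosome 19 too. That chromosome was picked after it was seen to be the only one to rise with siSUV420H1 without overlap of the groups. Its rise passed adjustment over the 27 location measures (exact permutation test, adjusted p = 0.0321). The lowest siSUV420H1 library held 8.16 Mb there against at most 6.90 Mb with siNC, which argues against enrichment weaker everywhere in that arm. With A-196 the lowest library there, at 6.52 Mb, lay below the highest DMSO library, at 7.35 Mb, whereas covered length on chromosome 22 (1.18 Mb ± 0.0448 with DMSO and 1.33 Mb ± 0.0892 with A-196) and in the outer 1 Mb of chromosomes (3.05 Mb ± 0.115 and 3.41 Mb ± 0.213) was higher in every A-196 library; these go against it, but they are 2 of 27 measures, picked after they were seen, and 3 libraries against 3 cannot pass a test (exact permutation p = 0.1 for each), so it stays open for A-196. A loss of the mark through SUV420H1, or with A-196 also through SUV420H2, may account for part of the pattern; the low likeness of the A-196 libraries to each other and the unknown depth keep it a hypothesis. In the siRNA arm the real split of the 8 libraries was the only 1 of 35 to give as many regions lost (3301, highest other 34), regions gained (279, highest other 34), genes lost (593, highest other 7) or genes gained (68, highest other 7), a share of 0.0286. That share holds only if the libraries of a group are independent, which the 3 dishes stated per condition leave open. Among the siSUV420H1 libraries, replicates 1 and 3 were most alike (Jaccard index 0.734), then replicates 2 and 4 (0.696). Chromosome X held 4.56 and 3.88 Mb in the former and 6.22 and 5.69 Mb in the latter. In the inhibitor arm the 10 splits are too few for a share under 0.05 (1615 and 286 regions with a highest other of 87, 353 and 161 genes with a highest other of 21).

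Zinc finger genes stayed marked in every library more often than other genes. A longer covered length over them in the controls did not account for it: 82.5% of 302 stayed marked with A-196 against a median of 57.6% and an upper 95% limit of 62.3% in sets matched on control covered length, and 94.7% of 341 with siSUV420H1 against 73.3% and 77.1%. That length was counted only within 2 kb of each gene. The full width of a peak that runs further, and its strength, were not matched, so these stay open. A property of chromosome 19 as a whole did not account for all of the difference, since zinc finger genes stayed marked more often within it. With A-196 it was 174 of 191 against 19 of 35 other genes (two-sided Fisher's exact p = 7.68e-07). With siSUV420H1 it was 195 of 197 against 33 of 44 (two-sided Fisher's exact p = 1.42e-07). On other chromosomes it was 75 of 111 against 617 of 1621, and 128 of 144 against 1409 of 2369. Genes of both kinds stayed marked more often on chromosome 19 than elsewhere, so a part played by the chromosome is not excluded. Other genes stayed marked in 54.3% there against 38.1% elsewhere with A-196, and in 75% against 59.5% with siSUV420H1. These counts were not matched on covered length. The data are consistent with a mark at zinc finger genes that depends less on the enzymes targeted; that is a hypothesis, no enzyme was tested on its own beyond SUV420H1, and neighbouring zinc finger genes are not independent.

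Gained genes were long in both arms, with medians of 240.7 kb (A-196) and 86.7 kb (siSUV420H1) against 24.5 kb for all genes. Placing the covered stretches that lay outside control peaks at random on their chromosomes, 200 times, gave gained genes with medians of 300.6 to 398.6 kb and 270.9 to 489 kb (central 95%), both above the observed medians, so length alone does not account for either set. Chance placement also gave a median of 222 gained genes in the inhibitor arm, more than the 161 observed, and 46 in the siRNA arm, fewer than the 68 observed (highest 63). A stretch common to every treated library was present in 56 of the 161 genes, against at most 6 by placement, and in 61 of 68, against at most 2. The 105 gained genes of the inhibitor arm without one had a median length of 358.8 kb, inside the 301.7 to 398.9 kb of such genes by placement, so length and scattered peaks may account for these; the 7 of the siRNA arm (99.9 kb) are too few to tell.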
